A study of Mus musculus with 9 samples.

How the data were processed

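Gene expression was measured in gastrocnemius, a calf muscle, of 9 mice, each hybridised to its own Affymetrix U74Av2 oligonucleotide array. Per the labels' protocols, total RNA was extracted from frozen tissue with Trizol and purified on RNeasy columns, copied into cDNA with SuperscriptII and a T7-dT24 primer, and transcribed into biotin-labelled cRNA with an Enzo kit. The deposited values are probe set intensities on a linear scale, and 19.4% to 29.9% of them were at or below 0 in each array, as after subtraction of a background or mismatch signal. The expression measure, the software and any scaling are not given in the sources used here. The scale factor of each array therefore stays unknown.

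The array medians of the deposited intensities, over 12422 probe sets that are not controls, were 14.9 in wild-type 1, 3.40 in wild-type 2, 2.85 in hDMD 1, 45.6 in hDMD mdx 1, 2.23 in hDMD mdx 2, 2.89 in mdx 1, 19.4 in mdx 2, 2.56 in mdx utrn-/- 1 and 1.47 in hDMD mdx utrn-/- 1. On the log2(value + 16) scale these medians spread over 1.82, above the tolerance of 0.1 set in the design, so the intensities were quantile normalised across the 9 arrays on the linear scale. Values below 0 were set to 0, a pseudocount of 16 was added, and log2 was taken, which puts the floor at 4. Fold changes are on this log2(value + 16) scale and understate the change of dim genes. Where every array of a group lay at the floor, both levels are given and no fold. The order of scaling and log was left open by the design, and scaling came first.

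Of the 12488 probe sets, 66 were controls and stayed out of the tests. Gene names came from the platform annotation, with symbols updated through Entrez gene identifiers. Of the 12422 other probe sets, 10833 carried 1 symbol, 396 carried several and 1193 were not listed and stay unnamed. Of those with 1 symbol, 10817 were matched to a current symbol and 16 kept the older one. Probe sets with a mean log2 value above the 40th percentile were kept, which left 7453, of which 6698 had 1 symbol, for 5666 genes. Of the kept values, 3.12% lay at the floor. A gene with several probe sets was represented by the one with the highest mean over all arrays.

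Each comparison was fitted with lmFit, contrasts.fit and eBayes of limma 3.58.1 in R 4.3.3, with 1 mean per genotype over all 9 arrays. The 3 genotypes with 2 mice gave the shared residual spread, on 3 degrees of freedom. A genotype with 1 mouse was assumed to vary like those. The contrast of the dystrophin-lacking with the dystrophin-carrying arrays used all 9 arrays in those classes, on 7 degrees of freedom. The contrast of human gene carriers with non-carriers on deficient backgrounds used 6 arrays with utrophin genotype as an additive term. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 7453 probe sets, and the threshold was 0.05. The single pair of utrophin-deficient mice had no test, and its list medians were ranked among 10000 random lists of the same size matched on mean expression.

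A total of 26 gene lists were fixed: macrophage and monocyte, T and B lymphocyte, neutrophil and mast cell, antigen presentation, complement, chemokines and receptors, interferon response, lysosome, extracellular matrix, regenerating and developing muscle, fast fibre contractile, slow fibre contractile, dystrophin complex and muscle membrane, cell cycle, oxidative phosphorylation, glycolysis and glycogen, fatty acid oxidation, adipocyte, endothelial and vessel wall, blood, nerve and Schwann cell, tendon and cartilage, immediate early and stress, muscle atrophy and proteolysis, circadian, and sex-linked genes. They were tested with camera of limma at its preset inter-gene correlation of 0.01, adjusted over the 26 lists. The tests were repeated with an estimated correlation and with fry. Some lists share genes: of the 25 macrophage genes kept, 5 also stand in another list, as do 3 of the 10 complement genes and 4 of the 30 regenerating muscle genes. List scores per array are the medians of the members' deviations from their means over the arrays.

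The samples, the tests, the lists, the named genes and most alternatives were fixed before the data were examined. Named genes were, for each comparison, up to 8 passing genes per direction whose arrays did not overlap between the groups, or, where none passed, the 3 with the smallest p per direction. To these were added up to 4 members with the largest change of each passing list, and a fixed set of muscle, macrophage and matrix genes in 3 comparisons. The alternatives fixed with them were deposited values without normalisation, no filter on dim probe sets, pseudocounts of 1 and 64, eBayes with a trend, only the compared arrays, age or the human gene as a covariate, the most variable probe set per gene, and each mouse left out in turn.

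The hybridisation spike-in controls, which are added to each sample in fixed amounts, were examined after the values had been seen. On 9 such probe sets, 3 arrays (wild-type 1, hDMD mdx 1 and mdx 2) had geometric mean intensities of 318 to 376, and the other 6 arrays had 42.1 to 62.0. These groups are called the bright and the dim arrays. Brightness as a block in the fits, a fit on the dim arrays alone, log2 before quantile normalisation, and the 100 probe sets with the smallest p where no probe set passed were added as alternatives after seeing the data. The block left 2 residual degrees of freedom, or 6 in the contrast of the 2 dystrophin classes. For arrays, their number limits the precision. The labels describe individual mice, and no mouse was measured more than once.

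The fits were tested on simulated data with 200 changed probe sets among 7453, drawn with the moderated residual spread of the real arrays. The simulated values were independent between genes and had no brightness groups and no floor. The shares and list p-values below therefore describe such data, and need not hold for the real arrays. In mdx against wild-type, 0% of changes of 1 log2 unit, 61.2% of changes of 2 and 89.4% of changes of 3 were recovered. In the contrast of the dystrophin classes the recovered shares were 35.8%, 94.0% and 100%. In the contrast of carriers on deficient backgrounds they were 5.97%, 83.6% and 98.5%. A simulated list shifted by 0.5 had an adjusted p of 0.223, 0.00122 and 0.0713 with an estimated correlation in these comparisons, in the same order. Figures were drawn with Python 3.11.15. No genome was used here.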

Results

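Transcript levels were compared in gastrocnemius muscle of 9 mice of 6 genotypes, each on 1 array. Mice of the mdx strain lack full-length dystrophin, the protein that links the fibre's cytoskeleton to its membrane and matrix. The hDMD mice carry the full-length human dystrophin gene, and utrn-/- mice lack utrophin, a related protein. The arrays came from wild-type (n = 2), hDMD (n = 1), mdx (n = 2), hDMD mdx (n = 2), mdx utrn-/- (n = 1) and hDMD mdx utrn-/- (n = 1) mice. Ages were 7 weeks for both wild-type mice, 11 for hDMD, 15 and 13 for mdx 1 and 2, 24 and 10 for hDMD mdx 1 and 2, 5 for mdx utrn-/- and 9 for hDMD mdx utrn-/-. All mice were male but wild-type 1. Age differed between genotypes. Both wild-type mice were younger than every mouse of the single genotypes compared with them, so age cannot be told apart from genotype in those comparisons. Values are quantile normalised probe set intensities on the log2(value + 16) scale, with a floor of 4, and errors are SD for levels and SE for differences.

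The female mouse, wild-type 1, had the highest Xist, the RNA that silences an X chromosome, at 5.20 against 4 to 4.54 in the males. Its Eif2s3y, a Y-linked gene, was at 4.03 against 5.06 to 5.98. The Dmd probe set lay between 4 and 4.95 in every array, and the Utrn probe sets lay between 4.15 and 6.16, so neither checks the genotype labels. The spike-in controls separated 3 bright arrays (wild-type 1, hDMD mdx 1 and mdx 2) from 6 dim ones, with medians 7.21 times apart. Three-prime to five-prime ratios, a sign of RNA integrity, followed the same division. For actin they were 1.20 to 1.87 in the bright and 0.669 to 0.908 in the dim arrays, and for Gapdh 1.18 to 1.53 and 0.951 to 1.12. The first principal component, with 38.8% of the variance, separated the same 3 arrays from the rest after normalisation. Wild-type, mdx and hDMD mdx each had 1 bright and 1 dim array, and the other genotypes only dim ones. Without a block, the residual spread of the genotype fits therefore holds the difference between bright and dim arrays as well as that between mice. A count of small p-values below the number by chance does not show an absence of change in these fits. Medians within the bright and the dim arrays are therefore given beside pooled ones. Differences of single genes have both values in parentheses, bright first, where the larger was over 1.5 times the smaller or their signs differed.

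**Figure D1:**
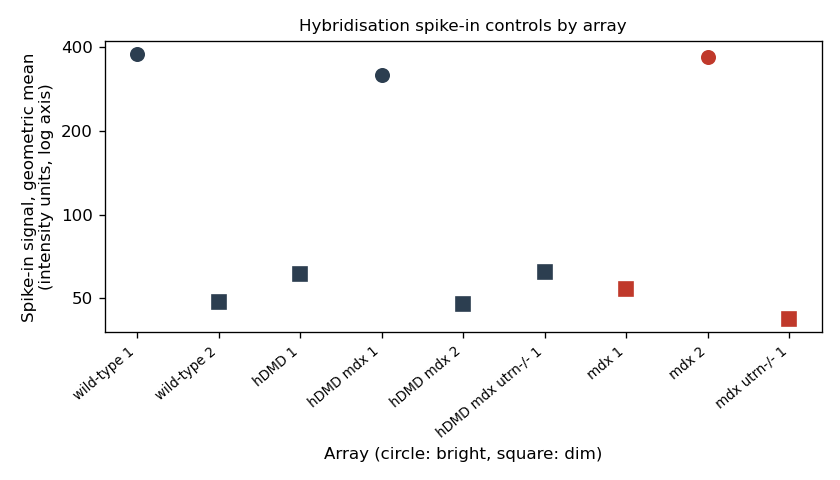
Geometric mean intensity of 9 hybridisation spike-in probe sets per array, on a log axis, with 1 point per array (circles for bright and squares for dim arrays, red for dystrophin-lacking and dark for dystrophin-carrying mice). The 3 bright arrays lie between 318 and 376 and the 6 dim arrays between 42.1 and 62.0.

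The first comparison asked which genes followed full-length dystrophin as given by the genotype, mouse or human. It set 3 arrays without it (mdx and mdx utrn-/-) against 6 arrays with it. Genes of embryonic and regenerating muscle were higher without dystrophin. Myl4 (Entrez gene 17896), the embryonic and atrial myosin light chain, rose by 2.44 ± 0.26, from 5.88 ± 0.36 (n = 6) to 8.32 ± 0.31 (n = 3), and by 3.18 ± 0.22 on its other probe set, which was singled out after its values were seen. Myh3 (Entrez 17883), the embryonic myosin heavy chain, rose by 2.24 ± 0.30, with 1.23 within the bright and 2.75 within the dim arrays. Tmsb10 (Entrez 19240), which binds actin monomers, rose by 1.93 ± 0.30, S100a4 (Entrez 20198), a calcium-binding protein of motile cells, by 1.88 ± 0.29, Lst1 (Entrez 16988), a leukocyte transcript at the floor in 4 of the 6 carrying arrays, by 1.67 ± 0.23 (1.09 and 1.95), and Mt2 (Entrez 17750), a metallothionein, by 1.90 ± 0.29.

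In limma, 9 of 7453 probe sets passed, all of them higher without dystrophin, and 416 had an unadjusted p under 0.05, against 373 by chance. The adjusted p was 0.00344 and 6.08e-05 for the Myl4 probe sets, 0.0203 for Myh3 and Lst1, 0.0369 for Mt2 and 0.0401 for Tmsb10 and S100a4 in limma. The remaining passing probe sets were Peg3, an imprinted gene, at 1.63 ± 0.26 with an adjusted p of 0.0435, and 1 without a gene name here, at 2.56 ± 0.36 with an adjusted p of 0.0239 in limma. Both were singled out after their values were seen, and the Peg3 probe set with the highest mean differed by 1.77 ± 0.42 and did not pass. With brightness as a block, 11 probe sets passed, all 9 among them, but in the 6 dim arrays alone 8 passed, 7 higher and 1 lower, with 4 of the 9 among them. There the Myl4 probe set at 2.44, Tmsb10, Mt2 and S100a4 differed by 2.46 ± 0.35, 1.93 ± 0.41, 1.66 ± 0.29 and 2.06 ± 0.28 and did not pass in limma with fewer arrays (adjusted p 0.0610, 0.292, 0.174 and 0.0524). With age as a covariate 7 of the 9 passed, and Tmsb10, at 1.93 ± 0.32 against 1.93 ± 0.30, did not (adjusted p 0.0801 in limma). Leaving out hDMD, hDMD mdx 2 or mdx utrn-/- left 2 passing probe sets each, mdx 1 left 3, hDMD mdx 1 or hDMD mdx utrn-/- gave 5, and leaving out wild-type 1 gave 18, 13 higher and 5 lower. Myl4 passed in limma with each mouse left out, with adjusted p up to 0.0458.

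The other named calls of the class comparison ended with some mice left out. Myh3, Tmsb10, Mt2, S100a4 and Lst1 had limma adjusted p values of 0.112, 0.227, 0.174, 0.227 and 0.134 without mdx 1, and of 0.115, 0.223, 0.223, 0.290 and 0.115 without mdx utrn-/-. In the same order they were 0.0587, 0.118, 0.0587, 0.118 and 0.0587 without hDMD, and 0.077, 0.126, 0.0829, 0.0940 and 0.0781 without hDMD mdx 2. Tmsb10 and Mt2 did not pass in limma without mdx 2 (adjusted p 0.163 each), nor did Tmsb10 and S100a4 without hDMD mdx 1 (0.112 and 0.0980). Without hDMD mdx utrn-/-, the adjusted p of Tmsb10, Mt2 and S100a4 was 0.0800 in limma. Over all mice left out in turn the differences were 1.94 to 2.66 for Myh3, 1.79 to 2.13 for Tmsb10, 1.75 to 2.0 for Mt2, 1.71 to 2.20 for S100a4 and 1.54 to 1.79 for Lst1. As deposited 0 probe sets passed in limma, with 12 at an unadjusted p under 0.05. With a pseudocount of 1, 1 passed, and the Myl4 probe set at 2.44 was at 2.81 ± 0.34 with an adjusted p of 0.0563 in limma. Without the filter or with the human gene as a covariate 2 passed, and Myh3, Tmsb10, Mt2, S100a4 and Lst1 did not. Without the filter their differences were as before and 12422 probe sets were tested, and with the covariate they were 2.27 ± 0.40, 1.55 ± 0.37, 1.74 ± 0.38, 1.67 ± 0.38 and 1.54 ± 0.30. With a pseudocount of 64, Myh3 was at 1.09 ± 0.17 with an adjusted p of 0.0518 in limma.

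**Figure D2:**
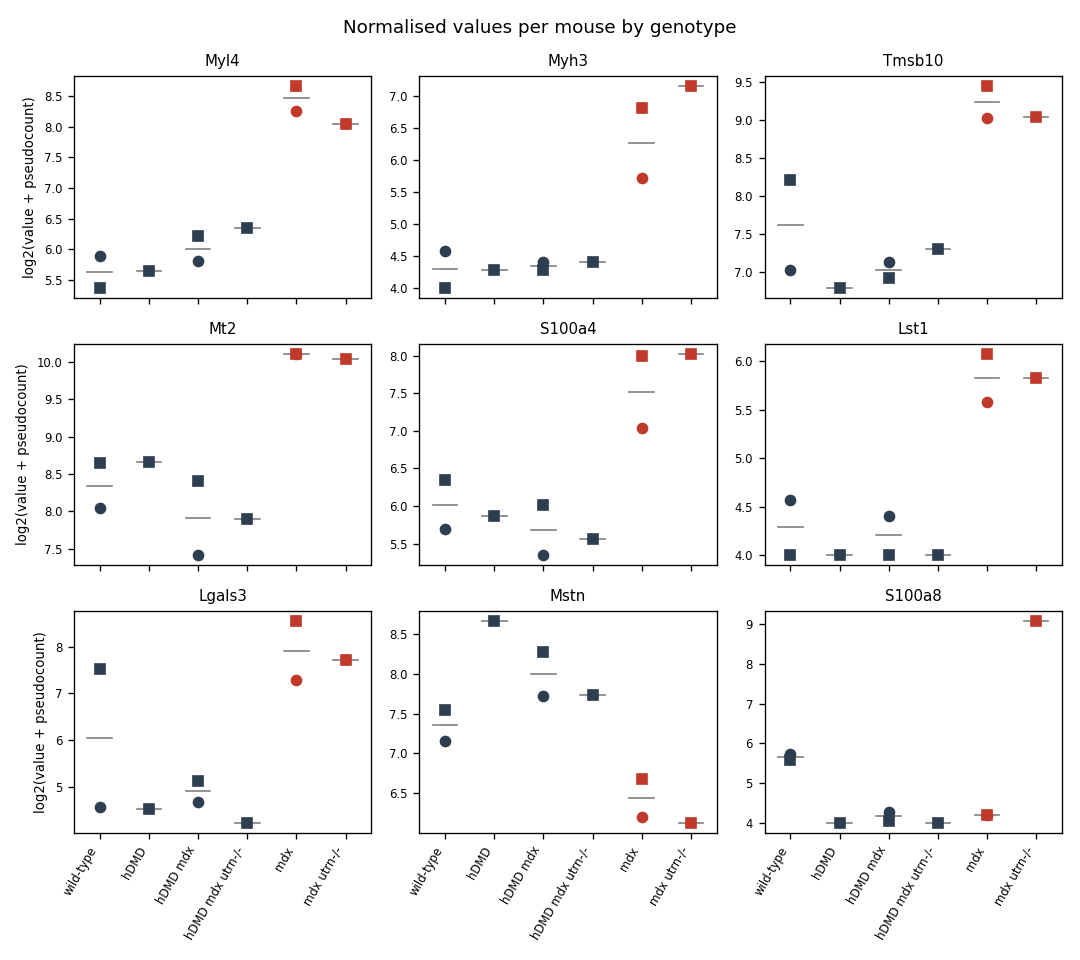
Normalised level on the log2 scale of 9 genes in each array, grouped by genotype (circles for bright and squares for dim arrays, red for dystrophin-lacking and dark for dystrophin-carrying mice, grey line for the genotype mean). Myl4 lies between 8.05 and 8.66 in the 3 arrays without dystrophin and between 5.38 and 6.34 in the 6 with it, and S100a8 is at 9.08 in mdx utrn-/- alone.

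Of 30 regenerating and developing muscle genes, 25 had higher values without dystrophin, with a median difference of 0.59. It was 0.70 within the bright and 0.72 within the dim arrays. The list had a camera adjusted p of 1.25e-15 and kept its call, with adjusted p = 0.00204 with an estimated correlation. Myl4 and Myh3 rose over all probe sets, and 11 members were higher and 1 lower when adjusted over the list alone. Among members that did not pass over all probe sets in limma, Chrna1 (Entrez 11435), a subunit of the acetylcholine receptor, differed by 2.06 ± 0.38 with an adjusted p of 0.104, and 0.00285 with the block. Igf2 (Entrez 16002), a fetal growth factor, differed by 3.60 ± 0.75 (1.48 and 4.66) and Mstn (Entrez 17700), the inhibitor of muscle growth myostatin, by -1.52 ± 0.32, both with an adjusted p of 0.199 in limma. Actc1 (Entrez 11464), cardiac actin, was at 10.27 ± 0.69 and 10.22 ± 0.43, a difference of 0.05 ± 0.33 (0.33 and -0.09).

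All 25 macrophage and monocyte genes had higher values without dystrophin, with a median of 0.73, 1.06 within the bright and 0.75 within the dim arrays. Their camera adjusted p was 3.96e-15, but adjusted p = 0.302 with an estimated correlation. None passed over all probe sets, and 6 did when adjusted over the list alone. Lgals3 (Entrez 16854), galectin-3 of activated macrophages, differed by 2.73 ± 0.62, Ctss (Entrez 13040), a lysosomal protease, by 2.22 ± 0.58, and Lyz2 (Entrez 17105), lysozyme, by 1.92 ± 0.54. All 15 antigen presentation genes had higher values, with a median of 0.52 (0.82 and 0.39 within the bright and dim arrays) and a camera adjusted p of 1e-05, and adjusted p = 0.402 with an estimated correlation, and Ctss alone was called when adjusted over the list alone. One wild-type array stood apart in these lists: wild-type 2 had a macrophage score of 0.80 and an adipocyte score of 1.59.

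Of 48 extracellular matrix genes, 38 had higher values without dystrophin, with a median of 0.34 (0.54 and 0.34 within the bright and dim arrays). The camera adjusted p was 1.82e-07, and adjusted p = 0.34 with an estimated correlation. S100a4 passed over all probe sets and 3 members when adjusted over the list alone. Against wild-type, the matrix median was 0.08 in mdx and did not pass camera (adjusted p 0.421). It was -0.52 in hDMD, -0.64 in hDMD mdx and -0.61 in hDMD mdx utrn-/-, so the class difference rests largely on low values in carriers of the human gene. The collagen genes Col1a1 (Entrez 12842) and Col3a1 (Entrez 12825) differed by 0.75 ± 0.45 and 0.51 ± 0.61 (1.68 and -0.07), and Timp1 (Entrez 21857), a protease inhibitor, by 1.76 ± 0.46. The 25 lysosome genes had a median of 0.39, with 0.38 within the bright and 0.35 within the dim arrays, a camera adjusted p of 5.06e-06, and adjusted p = 0.302 with an estimated correlation. With the human gene as a covariate the matrix median was -0.04, and camera no longer called the matrix (adjusted p = 0.908), antigen presentation (0.404), lysosome (0.0722), glycolysis (0.0626), complement (0.223) or stress (0.63) lists. Of the 84 splits of the 9 arrays into 3 and 6, 21 gave at least as many passing lists as the 9 found here.

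Glycolysis and glycogen genes had lower values without dystrophin in 17 of 22 cases, with a median of -0.22 (-0.10 and -0.25 within the bright and dim arrays). The camera adjusted p was 0.0006, with adjusted p = 0.302 with an estimated correlation. Phka1 (Entrez 18679), a subunit of the kinase that starts glycogen breakdown, differed by -1.04 ± 0.22 (-0.76 and -1.19) and was the only member called when adjusted over the list alone. Fbp2 (Entrez 14120), a muscle enzyme of sugar synthesis, differed by -0.99 ± 0.35. Of 24 fatty acid oxidation genes, 21 had lower values, with a median of -0.19 (-0.16 and -0.19 within the bright and dim arrays), a camera adjusted p of 0.00919, and adjusted p = 0.34 with an estimated correlation. The 34 immediate early and stress genes had a median of 0.24 (0.03 and 0.30), a camera adjusted p of 0.00443, and adjusted p = 0.426 with an estimated correlation. Of these, Mt2 passed over all probe sets and 2 members when adjusted over the list alone. The 10 complement genes had a median of 0.28 (0.65 and 0.09), a camera adjusted p of 0.00906, and adjusted p = 0.474 with an estimated correlation, with C3ar1 called when adjusted over the list alone. Without mdx utrn-/-, the stress list had an adjusted p of 0.157 in camera. The complement list lost its call in camera without wild-type 1, hDMD mdx 1 or mdx 1 (adjusted p 0.0756, 0.0588 and 0.137), and the fatty acid oxidation list without hDMD mdx 1 or mdx 1 (0.0588 and 0.0831). The complement list also lost it with a pseudocount of 1 (0.17, adjusted p 0.0713) and in the dim arrays alone (0.09, 0.380).

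The other 17 lists did not pass camera in this comparison. Median differences were 0.54 for neutrophil and mast cell genes, -0.32 for T and B lymphocyte genes and 0.33 for chemokines and receptors, each with an adjusted p of 0.0571. Fast fibre contractile genes were at -0.10, slow fibre contractile genes at 0.04, oxidative phosphorylation genes at -0.04, and muscle atrophy and proteolysis genes at -0.14. The medians of cell cycle, interferon response, circadian and blood genes were 0.04, 0.16, -0.26 and 0.29. Adipocyte genes were at -0.06, tendon and cartilage genes at -0.11, endothelial and vessel wall genes at -0.08, and nerve and Schwann cell genes at 0.00. Sex-linked genes were at 0.16, and genes of the dystrophin complex and muscle membrane at -0.01.

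**Figure D3:**
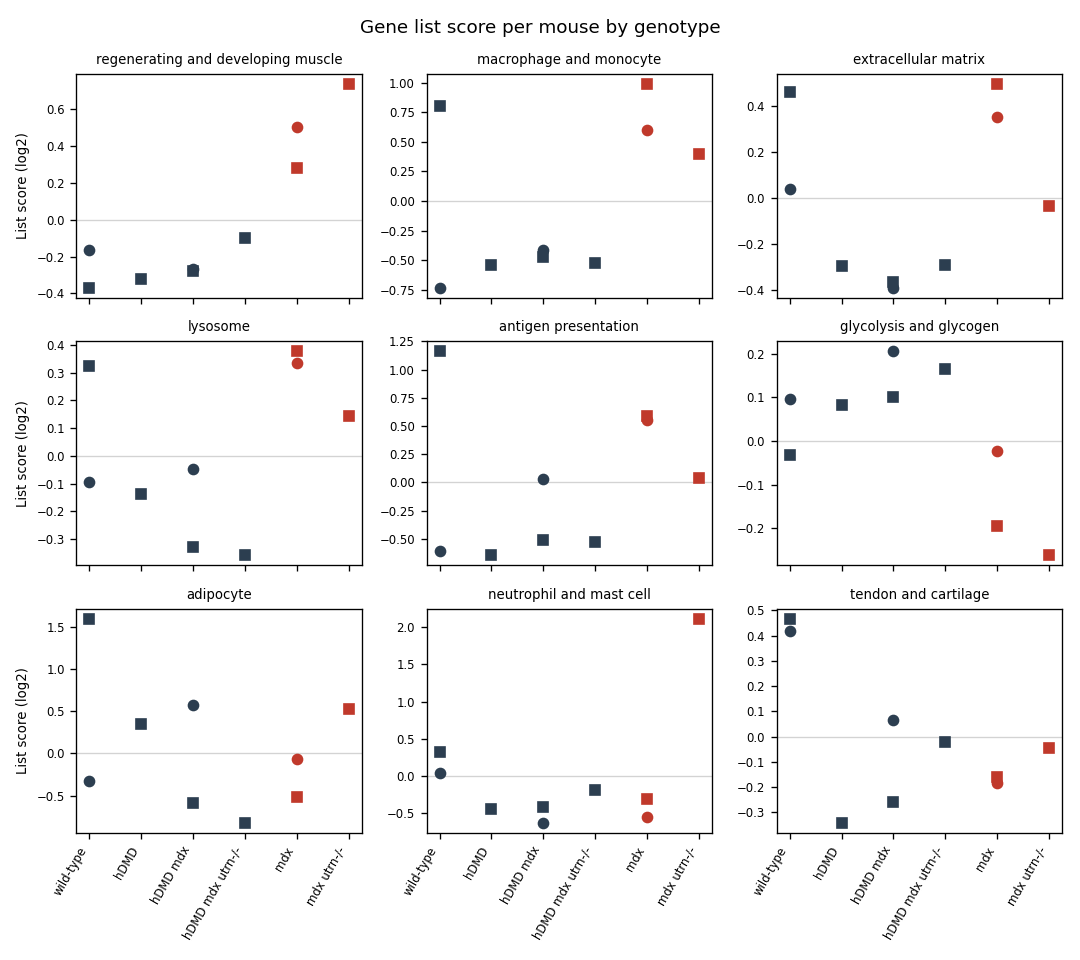
Score of 9 gene lists per array, the median log2 deviation of the members from their means over all arrays, grouped by genotype (circles for bright and squares for dim arrays, red for dystrophin-lacking and dark for dystrophin-carrying mice). The regenerating muscle score is above 0.27 in the 3 arrays without dystrophin and below -0.09 in the 6 others, and the neutrophil score is 2.11 in mdx utrn-/-.

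Mice of the mdx genotype were compared with wild-type to see the change with loss of mouse dystrophin (n = 2 each). Both mdx mice were older than the wild-type mice, so the differences can belong to age as well as to genotype. Myl4 was at 8.46 ± 0.28 in mdx and 5.63 ± 0.36 in wild-type, a difference of 2.83 ± 0.37, with 2.37 within the bright and 3.28 within the dim arrays. Mt1 (Entrez 17748), a metallothionein, differed by 2.10 ± 0.35, Mmp12 (Entrez 17381), macrophage elastase, by 1.93 ± 0.42 (2.34 and 1.52), and Chrna1 by 2.15 ± 0.63 (1.64 and 2.66). S100a8 (Entrez 20201), a calcium-binding protein of neutrophils, was at 4.19 ± 0.01 in mdx and 5.67 ± 0.10 in wild-type. Slc6a2 (Entrez 20538), a noradrenaline transporter, and Sla (Entrez 20491), an adaptor protein of lymphocytes, were at the floor in both mdx arrays and at 5.50 ± 0.36 and 5.33 ± 0.11 in wild-type. None of these genes passed: limma called 0 of 7453 probe sets, with or without the block, 130 had an unadjusted p under 0.05, fewer than the 373 by chance, and the smallest adjusted p was 0.342. With the block, 427 had an unadjusted p under 0.05 in limma.

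Regenerating and developing muscle genes had higher values in mdx in 26 of 30 cases, with a median of 0.46 (0.47 and 0.62 within the bright and dim arrays). The camera adjusted p was 1.29e-09, with adjusted p = 0.171 with an estimated correlation, and Myl4 alone was called when adjusted over the list alone. Igf2 differed by 2.24 ± 0.82 (0.42 and 4.06) and Myh3 by 1.98 ± 0.46 (1.14 and 2.81). All 13 neutrophil and mast cell genes had lower values in mdx, with a median of -0.56 (-0.41 and -0.54), a camera adjusted p of 5.14e-06, and adjusted p = 0.171 with an estimated correlation. S100a8 was the only member called when adjusted over the list alone. Tendon and cartilage genes were lower in 6 of 7 cases, with a median of -0.45 (-0.66 and -0.51), a camera adjusted p of 0.000421, and adjusted p = 0.233 with an estimated correlation. Among them, Chad (Entrez 12643), chondroadherin, differed by -1.93 ± 0.53 and Fmod (Entrez 14264), fibromodulin, by -1.11 ± 0.43.

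The macrophage list had a median of 0.62, but 1.26 within the bright and 0.08 within the dim arrays, with a camera adjusted p of 1.54e-07 and adjusted p = 0.59 with an estimated correlation. Lgals3 differed by 1.86 ± 0.92 (2.72 and 1.01), Ctss by 1.64 ± 0.52 (2.48 and 0.80), Cd68 (Entrez 12514), a lysosomal protein of macrophages, by 1.14 ± 0.63 (1.49 and 0.79) and Lyz2 by 1.16 ± 0.57 (1.70 and 0.63). Without wild-type 1 the macrophage median was 0.07, and camera gave an adjusted p of 0.797 in the other direction. Adipocyte genes differed by a median of -0.72, with 0.38 within the bright and -2.07 within the dim arrays, a camera adjusted p of 2.48e-05, and adjusted p = 0.59 with an estimated correlation. Fasn (Entrez 14104), fatty acid synthase, differed by -1.48 ± 0.75 (-0.47 and -2.49) and Me1 (Entrez 17436), malic enzyme, by -1.44 ± 0.50 (-1.11 and -1.77). Without wild-type 2 the adipocyte median was 0.23, with an adjusted p of 0.166 in camera. Lysosome genes had a median of 0.19 (0.46 and 0.00), a camera adjusted p of 0.0169 and adjusted p = 0.656 with an estimated correlation. Without wild-type 1 its median was -0.09, and without mdx 1 its adjusted p was 0.21 in camera.

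Extracellular matrix genes did not pass camera in mdx against wild-type (adjusted p 0.421). Of 48, 26 had higher values and 22 lower, with a median of 0.08 (0.27 and -0.12 within the bright and dim arrays). Col1a1 differed by -0.23 ± 0.34 (-0.31 and -0.15). Fatty acid oxidation genes had a median of -0.26 (-0.13 and -0.44), a camera adjusted p of 0.0225, and adjusted p = 0.59 with an estimated correlation. Chemokines and receptors had a median of 0.44 (0.38 and 0.00), a camera adjusted p of 0.0395, and adjusted p = 0.488 with an estimated correlation. Among them Ccl8 (Entrez 20307), a monocyte attractant, differed by 1.90 ± 0.64 (3.15 and 0.66). With the block the chemokine list did not pass camera (adjusted p = 0.116) and the oxidative phosphorylation list did (0.0329, and 0.0873 without the block). Camera did not call the fatty acid oxidation list without wild-type 2 or mdx 1 (adjusted p 0.319 and 0.333), nor the chemokine list without wild-type 1 or mdx 2 (0.361 and 0.347). Without the filter the tendon and chemokine medians were -0.20 and 0.05, and neither list passed camera (adjusted p 0.0602 and 0.0621). With a pseudocount of 1, neither the chemokine (0.77, adjusted p 0.125), the fatty acid oxidation (-0.32, 0.0620) nor the lysosome list (0.24, 0.0628) passed camera, nor did the lysosome list with the most variable probe set per gene (0.15, 0.0893). No member of the macrophage, adipocyte, tendon, lysosome, fatty acid oxidation or chemokine lists was called when adjusted over the list alone.

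The human gene on the mdx background was the subject of the hDMD mdx against mdx comparison (n = 2 each). Myl4 was at 6.01 ± 0.28 in hDMD mdx and 8.46 ± 0.28 in mdx, a difference of -2.45 ± 0.37, and -2.45 within both the bright and the dim arrays. Mt1 differed by -2.38 ± 0.35 and Mmp12 by -2.28 ± 0.42. Myostatin differed by 1.57 ± 0.38, from 6.43 ± 0.34 in mdx to 8.0 ± 0.39, and Rxrg (Entrez 20183), a retinoid receptor, by 1.81 ± 0.47 (0.90 and 2.73). Pla2g1b (Entrez 18778), a secreted phospholipase, was at the floor in both mdx arrays and at 6.08 ± 0.62 in hDMD mdx. No single gene passed, since limma called 0 of 7453 probe sets with or without the block, 215 had an unadjusted p under 0.05, fewer than the 373 by chance, and the smallest adjusted p was 0.629. The block raised the 215 to 543 in limma.

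Extracellular matrix genes had lower values in hDMD mdx in 40 of 48 cases, with a median of -0.80 (-0.70 and -0.89 within the bright and dim arrays). The camera adjusted p was 6.24e-19, with adjusted p = 0.267 with an estimated correlation, and 0 members were called when adjusted over the list alone. Timp1 differed by -2.40 ± 0.69, Postn (Entrez 50706), periostin, by -1.97 ± 0.45, S100a4 by -1.83 ± 0.47 and Col1a1, the main collagen chain of scar and tendon, by -1.56 ± 0.34. All 25 macrophage genes had lower values, with a median of -0.95 (-0.81 and -1.52), a camera adjusted p of 5.58e-17, and adjusted p = 0.434 with an estimated correlation. Ctss, the only macrophage gene called when adjusted over the list alone, differed by -2.54 ± 0.52, Lgals3 by -3.01 ± 0.92, Tyrobp (Entrez 22177), a signalling adaptor of myeloid cells, by -1.98 ± 0.50 (-1.45 and -2.51) and Lyz2 by -1.91 ± 0.57 (-1.46 and -2.36).

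Regenerating and developing muscle genes had lower values in 25 of 30 cases, with a median of -0.71 (-0.96 and -0.50), a camera adjusted p of 1.09e-10, and adjusted p = 0.267 with an estimated correlation. Adjusted over the list alone, 7 were lower and 1 was higher. Igf2 differed by -3.27 ± 0.82 (-2.55 and -3.98), Chrna1 by -2.24 ± 0.63 and Myh3 by -1.93 ± 0.46 (-1.32 and -2.54). Lysosome genes had a median of -0.57 (-0.44 and -0.74), a camera adjusted p of 5.71e-08, and adjusted p = 0.434 with an estimated correlation. Lgmn (Entrez 19141), a lysosomal protease, differed by -1.63 ± 0.40. All 15 antigen presentation genes had lower values, with a median of -0.79 (-0.50 and -1.15), a camera adjusted p of 1.23e-07, and adjusted p = 0.68 with an estimated correlation. Of these, Ctss alone was called when adjusted over the list alone, and none of the lysosome genes.

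Complement genes had a median of -0.64 (-0.65 and -0.68), a camera adjusted p of 0.000791, and adjusted p = 0.68 with an estimated correlation. Glycolysis and glycogen genes had higher values in 19 of 22 cases, with a median of 0.17 (0.15 and 0.21), a camera adjusted p of 0.00224, and adjusted p = 0.282 with an estimated correlation. Phka1 differed by 0.95 ± 0.31 and Gpd2 (Entrez 14571), a mitochondrial enzyme of the glycerol phosphate shuttle, by 0.81 ± 0.33. Fatty acid oxidation genes had a median of 0.21 (0.28 and 0.11), a camera adjusted p of 0.0223, and adjusted p = 0.68 with an estimated correlation. These 3 lists lost their camera calls without hDMD mdx 1 (adjusted p 0.292, 0.112 and 0.752) or without mdx 1 (0.0917, 0.0896 and 0.392), in the order given, and had 0 members called when adjusted over the list alone.

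The fold changes of mdx against wild-type and of hDMD mdx against mdx had opposite signs for 69.9% of the 7453 probe sets, with Pearson's r of -0.618 across genes, which are not independent replicates. Both comparisons use the mdx arrays, and in 100 simulations of unchanged groups r averaged -0.499 (-0.528 to -0.454), with 66.7% of opposite sign. The covariance was -0.108, against -0.154 in simulations with the residual spread and -0.0737 with the spread left by the block. Myl4, Mt1, Myh3 and Chrna1 were each among the genes with opposite signs. No probe set passed limma in either comparison (130 and 215 with an unadjusted p under 0.05), so lists of passing genes could not be compared. With 2 mdx mice, a split would leave 1 array on each side and none was made, so the part owed to the shared arrays stays unknown.

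The hDMD mdx mice were also compared with wild-type, to see how far transgenic mdx muscle stood from normal (n = 2 each). Col1a1 was at 7.96 ± 0.29 in hDMD mdx and 9.75 ± 0.08 in wild-type, a difference of -1.79 ± 0.34, and Sparc (Entrez 20692), a collagen-binding protein, differed by -1.31 ± 0.32. Col1a2 (Entrez 12843) differed by -1.81 ± 0.49, whereas its other probe set was at 0.411. S100a8 differed by -1.51 ± 0.32, and Cmbl (Entrez 69574), a hydrolase, by 1.62 ± 0.43 (2.10 and 1.14). Elovl1 (Entrez 54325), an enzyme of fatty acid elongation, and Ankrd33b (Entrez 67434) were at the floor in both wild-type arrays and at 5.90 ± 1.17 and 5.13 ± 0.07 in hDMD mdx. None passed: limma called 0 of 7453 probe sets with or without the block, and 62 had an unadjusted p under 0.05, fewer than the 373 by chance. The block raised the 62 to 246 in limma.

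Matrix genes had lower values than in wild-type in 45 of 48 cases, with a median of -0.64 (-0.44 and -0.81 within the bright and dim arrays). The camera adjusted p was 3.43e-23, with adjusted p = 0.201 with an estimated correlation, and 0 members were called when adjusted over the list alone. Tendon and cartilage genes moved with them, with a median of -0.47 (-0.53 and -0.66), a camera adjusted p of 0.00509 and adjusted p = 0.397 with an estimated correlation. Camera did not call the tendon list without wild-type 1 or hDMD mdx 1 (adjusted p 0.212 and 0.183). Neutrophil and mast cell genes had a median of -0.52 (-0.45 and -0.74), a camera adjusted p of 6.39e-08, and adjusted p = 0.201 with an estimated correlation. S100a8 alone was called when adjusted over the list alone. The regenerating muscle genes had a median of -0.06 (-0.16 and 0.20) and did not pass camera, with an adjusted p of 0.604.

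Macrophage genes had a median of -0.59, with 0.17 within the bright and -1.37 within the dim arrays, a camera adjusted p of 1.44e-05, and adjusted p = 0.697 with an estimated correlation. The medians were -0.54 for antigen presentation (0.57 and -1.72), -0.39 for lysosome (0.09 and -0.71) and -0.43 for adipocyte genes (0.78 and -2.11). Their camera adjusted p values were 2.64e-05, 0.000175 and 0.00217, each with adjusted p = 0.697 with an estimated correlation. Without wild-type 2 the medians of the macrophage, antigen presentation, lysosome and adipocyte genes were 0.23, 0.16, -0.15 and 0.16, and camera reversed the direction of all 4, although the lysosome median stayed below 0. Without hDMD mdx 2 the adipocyte median was 0.02, with an adjusted p of 0.815 in camera. Immediate early and stress genes had a median of -0.27 (-0.30 and -0.03) and oxidative phosphorylation genes of 0.13 (0.00 and 0.30). Camera gave adjusted p values of 0.0132 and 0.023, again with adjusted p = 0.697 with an estimated correlation for both. Without wild-type 1 the stress median was 0.10, and without wild-type 2 the oxidative phosphorylation median was -0.06. Neither passed camera without hDMD mdx 1 (adjusted p 0.0913 and 0.552), nor the stress list without hDMD mdx 2 (0.131). The oxidative phosphorylation list did not pass camera as deposited (0.57, adjusted p 0.323), with a pseudocount of 1 (0.14, 0.141) or with the most variable probe set per gene (0.13, 0.0585). None of these 6 lists had a member called when adjusted over the list alone. With the block, complement and blood genes also passed camera, at an adjusted p of 0.0444 each.

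The single hDMD mouse showed the human gene on a normal background, against 2 wild-type mice. Hspa1b (Entrez 15511) and Hspa1a (Entrez 193740), inducible heat shock proteins, were at 7.85 and 8.04 in hDMD and at 4.74 ± 0.19 and 5.27 ± 0.28 in wild-type. Fmod, a collagen-binding proteoglycan of tendon, was at 5.03 against 8.02 ± 0.55, a difference of -2.98 ± 0.52, and Col1a1 differed by -1.74 ± 0.42. Siah1-ps1 (Entrez 20435), a pseudogene, differed by 2.42 ± 0.64, while Pagr1a (Entrez 67278) and S100a8 lay at the floor in hDMD and at 6.50 ± 0.73 and 5.67 ± 0.10 in wild-type. No gene passed: limma called 0 of 7453 probe sets with or without the block, and 136 had an unadjusted p under 0.05, fewer than the 373 by chance. The hDMD mouse was assumed to vary like the genotypes with 2 mice, and it has no replicate check.

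Matrix genes had lower values in hDMD than in wild-type in 46 of 48 cases, with a median of -0.52 and -0.84 against wild-type 2, the dim array. The camera adjusted p was 1.86e-09, with adjusted p = 0.439 with an estimated correlation, and Fmod, also a tendon gene, alone was called when adjusted over the list alone. Tendon and cartilage genes had a median of -0.57 (-0.70 within the dim arrays), a camera adjusted p of 0.000709 and adjusted p = 0.381 with an estimated correlation. Neutrophil and mast cell genes had a median of -0.65 (-0.73), a camera adjusted p of 0.00043 and adjusted p = 0.381 with an estimated correlation. Macrophage (-0.48), antigen presentation (-0.83), lysosome (-0.29) and oxidative phosphorylation genes (0.12) had camera adjusted p values of 5.99e-05, 5.99e-05, 0.0285 and 0.0372, each with adjusted p = 0.772 with an estimated correlation. Within the dim arrays their medians were -1.26, -2.28, -0.64 and 0.36. Without wild-type 2 the medians of the first 3 were 0.10, -0.10 and -0.13, and camera reversed their direction. None of the macrophage, antigen presentation, lysosome or oxidative phosphorylation genes was called when adjusted over the list alone. Without wild-type 2, camera also no longer called the neutrophil or oxidative phosphorylation lists (adjusted p 0.0966 and 0.832). Other settings ended calls in camera too. They were no filter for tendon (-0.10, adjusted p 0.177), as deposited for macrophage (-0.86, 0.445), a pseudocount of 1 for lysosome (-0.31, 0.0718) and oxidative phosphorylation (0.12, 0.190), and the most variable probe set per gene for the same 2 lists (-0.29, 0.0535, and 0.12, 0.0575). As deposited, camera reversed the neutrophil and oxidative phosphorylation lists. With the block, slow fibre and complement genes also passed camera, with adjusted p values of 2.13e-05 and 0.00274.

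On both deficient backgrounds together, 3 mice with the human gene were compared with 3 without, with utrophin genotype as a term. Lgals3 was at 4.68 ± 0.45 with and 7.85 ± 0.64 without the human gene, a difference of -3.16 ± 0.39 (-2.61 and -3.44 within the bright and dim arrays). Ctss differed by -2.62 ± 0.33 (-2.36 and -2.75), Tmsb10 by -2.04 ± 0.28 and Igf2 by -4.42 ± 0.69 (-2.55 and -5.36). Igf2 lay at the floor in hDMD mdx utrn-/-, the array with the weakest deposited signal. Myostatin differed by 1.58 ± 0.30 and Odc1 (Entrez 18263), the first enzyme of polyamine synthesis, by 1.44 ± 0.29. Ighm (Entrez 16019), the immunoglobulin mu chain, differed by 1.26 ± 0.27, but its other probe sets were at -1.03, 0.272 and 2.35.

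None of these passed in limma, where 0 of 7453 probe sets were called, 409 had an unadjusted p under 0.05, against 373 by chance, and the smallest adjusted p was 0.0649. With brightness as a block 4 probe sets passed, all lower with the human gene. Lgals3 and Ctss were among these, with an adjusted p of 0.136 without and 0.023 with the block in limma.

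The macrophage list was lower with the human gene in 23 of 25 genes, with a median of -0.88 (-0.81 and -1.08), a camera adjusted p of 3.61e-21 and adjusted p = 0.112 with an estimated correlation. Adjusted over the list alone, 13 macrophage genes were lower. Matrix genes had a median of -0.58 (-0.70 and -0.51), with 7 lower when adjusted over the list alone, and regenerating muscle genes -0.57 (-0.96 and -0.60), with 10 lower and 1 higher. Their camera adjusted p values were 4.15e-13 and 5.3e-12, with adjusted p = 0.161 and 0.112 with an estimated correlation. Myh3 differed by -2.21 ± 0.37 (-1.32 and -2.65) and S100a4 by -2.04 ± 0.37. Antigen presentation genes had a median of -0.74 (-0.50 and -0.82) and lysosome genes of -0.56 (-0.44 and -0.62), with camera adjusted p values of 3.95e-11 and 6.25e-08, and adjusted p = 0.161 with an estimated correlation for both. Adjusted over the list alone, 2 antigen presentation genes and 1 lysosome gene were lower.

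Glycolysis and glycogen genes had higher values with the human gene in 18 of 22 cases, with a median of 0.29 (0.15 and 0.29), a camera adjusted p of 0.00101, and adjusted p = 0.239 with an estimated correlation. Phka1 differed by 1.13 ± 0.27. Immediate early and stress genes (-0.42) and complement genes (-0.41) both had a camera adjusted p of 0.00026, with adjusted p = 0.533 and 0.394 with an estimated correlation. Within the bright and dim arrays the stress medians were -0.13 and -0.43, and the complement medians -0.65 and -0.31. Neutrophil genes had a median of -0.66, with 0.06 within the bright and -1.01 within the dim arrays, a camera adjusted p of 0.00614 and adjusted p = 0.533 with an estimated correlation. T and B lymphocyte genes had a median of 0.33 (0.08 and 0.29), a camera adjusted p of 0.0329 and adjusted p = 0.292 with an estimated correlation. Without either utrophin-deficient mouse the neutrophil median was 0.01 and the stress median -0.04, and neither list passed camera (adjusted p 0.859 and 0.365). The lymphocyte list lost its call without any 1 of the 4 mice with utrophin (camera adjusted p 0.0527 to 0.0811), and the complement list without hDMD mdx 1 (0.112). Without the filter neither the neutrophil (-0.29, adjusted p 0.0590) nor the lymphocyte list (0.04, 0.570) passed camera, nor the lymphocyte list with a pseudocount of 1 (0.68, 0.0547) or the most variable probe set per gene (0.26, 0.150). Adjusted over the list alone, 2 stress genes (Mt1 and Mt2) and 3 complement genes were lower, and Ighm was higher. By fry, which tests whether a list's genes move one way, the macrophage, regenerating muscle, glycolysis and lymphocyte lists passed at an adjusted p of 0.033, and the matrix, antigen presentation and lysosome lists at 0.0399.

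Loss of utrophin on top of dystrophin was seen in 1 mdx utrn-/- mouse of 5 weeks against 2 mdx mice of 13 and 15 weeks. S100a9 (Entrez 20202) and S100a8, the paired calcium-binding proteins of neutrophils, rose by 5.26 ± 0.42 and 4.89 ± 0.39, to 9.52 and 9.08 from 4.25 ± 0.29 and 4.19 ± 0.01. Against mdx 1, the dim array, the differences were 5.06 and 4.88. Ngp (Entrez 18054), a neutrophil granule protein, differed by 2.95 ± 0.58, and Mpo (Entrez 17523), the neutrophil peroxidase, by 2.87 ± 0.60. Among stretch-responsive muscle genes, Csrp3 (Entrez 13009) differed by 2.01 ± 0.76 and Ankrd1 (Entrez 107765) by 1.45 ± 0.44.

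Only S100a8 and S100a9 passed in limma, each with an adjusted p of 0.0195, among 286 probe sets with an unadjusted p under 0.05, fewer than the 373 by chance. With the block, 2 probe sets were higher and 1 was lower. Without mdx 1 or without mdx 2 no probe set passed in limma (218 or 172 with an unadjusted p under 0.05), and the adjusted p of S100a8 and S100a9 was 0.218 or 0.221, with differences of 4.88 to 5.47. The count was also 0 as deposited and with a pseudocount of 1 (2 and 407 with an unadjusted p under 0.05), where S100a9 was at 3.90 ± 1.90 and 7.77 ± 0.99. Without the filter, with 12422 probe sets tested, it was 6, S100a8 among them but not S100a9, at 5.26 ± 0.26 (adjusted p 0.063 in limma). The single mouse was assumed to vary like the genotypes with 2.

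Neutrophil and mast cell genes had higher values in mdx utrn-/- in 10 of 13 cases, with a median of 2.42 (2.36 within the dim arrays), a camera adjusted p of 1.21e-15, and adjusted p = 0.0775 with an estimated correlation. Adjusted over the list alone, 9 were higher. The 3 members without higher values were the mast cell proteases Cma1, at 4.90 against 5.23 and 5.28 in mdx, Cpa3, at the floor against 4.17 and 4.87, and Tpsb2, at the floor against 4.64 and 4.13, singled out after their values were seen. Slow fibre contractile genes had a median of 1.07 (1.88), a camera adjusted p of 0.00869 and adjusted p = 0.686 with an estimated correlation. Without mdx 1 their median was 0.21, with an adjusted p of 0.509 in camera, and Myh7 (Entrez 140781), the slow myosin heavy chain, differed by 1.52 ± 1.74. The medians were 0.35 (0.39) for stress, 0.33 (0.40) for regenerating muscle, -0.34 (-0.35) for matrix and -0.50 (-0.75) for macrophage genes. Their camera adjusted p values were 0.00869, 0.0386, 0.0182 and 0.0331, each with adjusted p = 0.686 with an estimated correlation. Without mdx 1 none of the 4 passed camera, with adjusted p values of 0.411, 0.248, 0.248 and 0.411. As deposited the stress (-0.65) and regenerating muscle lists (-0.73) did not pass camera (adjusted p 0.307 each), which still placed them above other genes. Without the filter neither the macrophage (-0.39, adjusted p 0.0679), the regenerating muscle (0.10, 0.215) nor the slow fibre list (1.07, 0.0505) passed camera. With a pseudocount of 1 neither the matrix (-0.40) nor the macrophage list (-0.56) passed, with an adjusted p of 0.0901 each in camera, nor the regenerating muscle list (0.40, 0.108). Adjusted over the list alone, only the blood list also had members called, in both directions. Fos (Entrez 14281), an immediate early gene, differed by 1.74 ± 0.52, and Postn by -1.21 ± 0.55. With the block, nerve and complement genes (adjusted p 0.00118 each) and antigen presentation genes (0.0427) also passed camera.

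The single hDMD mdx utrn-/- mouse was compared with wild-type (n = 2). Its array had the weakest deposited signal, with a mean intensity of 9.06 against 16.6 to 20.5 in the other dim arrays. Its spike-in controls, at 62.0, were the highest of the dim arrays. Fn1 (Entrez 14268), fibronectin, was at 6.09 against 8.63 ± 0.49 and Fmod at 5.17 against 8.02 ± 0.55, differences of -2.53 ± 0.50 and -2.85 ± 0.52, and Ctss differed by -2.43 ± 0.64. Mt1 and Lsp1 (Entrez 16985), a leukocyte protein, were at the floor in this mouse and at 6.80 ± 0.12 and 6.84 ± 0.62 in wild-type. Psmc4 (Entrez 23996), a proteasome subunit, differed by 2.47 ± 0.45, Sh2b3 (Entrez 16923), a signalling adaptor, by 2.34 ± 0.50 and Rdh13 (Entrez 108841), a retinol dehydrogenase, by 1.92 ± 0.46. None passed: limma called 0 of 7453 probe sets with or without the block, 529 had an unadjusted p under 0.05, against 373 by chance, and the smallest adjusted p was 0.691. Without the filter on dim probe sets, 3 passed in limma.

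Matrix genes had a median of -0.61 (-0.80 within the dim arrays), with Fn1 and Fmod lower when adjusted over the list alone, and stress genes of -0.85 (-0.25), with Mt1 lower. Both lists had a camera adjusted p of 0.000378, and adjusted p = 0.775 with an estimated correlation. Adipocyte genes had a median of -1.56 (-2.66), macrophage genes of -0.56 (-1.39), antigen presentation genes of -0.74 (-1.81) and lysosome genes of -0.50 (-0.77). Their camera adjusted p values were 0.00228, 0.00595, 0.00595 and 0.0474, each with adjusted p = 0.775 with an estimated correlation. Fabp4 (Entrez 11770), a fatty acid carrier of fat cells, differed by -2.27 ± 0.94. Without wild-type 2, camera called neither the matrix list (-0.32, adjusted p 0.261) nor the adipocyte (0.09, 0.597), macrophage (0.10, 0.822), antigen presentation (0.18, 0.812) or lysosome list (-0.15, 0.818). Neither the antigen presentation (-0.75, adjusted p 0.0811) nor the lysosome list (-0.51, 0.103) passed camera with a pseudocount of 1, nor the lysosome list with log2 taken first (-0.39, 0.0602). As deposited, camera reversed the macrophage list. With the block, blood, complement and slow fibre genes also passed camera (adjusted p 0.0116, 0.0303 and 0.0111).

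The utrophin-deficient pair, 1 mouse with and 1 without the human gene, had no test and no replicate check. The hDMD mdx utrn-/- array had the weakest deposited signal, so an effect of the human gene cannot be told apart there from weak signal at the floor. Igf2 was at the floor in hDMD mdx utrn-/- and at 10.73 in mdx utrn-/-, Csrp3 at the floor and at 8.91, and Lyz2 at the floor and at 7.16. Myh3 was at 4.40 and 7.16, Lgals3 at 4.23 and 7.71, S100a9 at 4.46 and 9.52, and Retn (Entrez 57264), the adipocyte hormone resistin, at 4.33 and 9.0. The median differences of the neutrophil (-2.26), adipocyte (-1.23), stress (-1.01), macrophage (-1.0) and regenerating muscle lists (-0.94) lay below all of 10000 random lists of like expression. Lysosome genes (-0.50) lay at percentile 0.14, antigen presentation genes (-0.57) at 0.51, matrix (-0.28), slow fibre (-0.53) and blood genes (-0.89) at 0.38, and glycolysis genes (0.43) at 99.54. Differences above 1 log2 unit were found for 1364 probe sets, 609 higher and 755 lower with the human gene, and as deposited for 582, 9 higher and 573 lower.

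No probe set passed in mdx against wild-type, so the reversal of mdx genes in this pair, on arrays that had no part in choosing them, could be described only over all probe sets and over the 100 with the smallest p. Over all 7453 probe sets 49.5% had opposite signs, with r of 0.018 across genes. Over the 100, Myl4 among them, it was 57%, with r of -0.155. Genes are not independent replicates, and no test was made.

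The effect of the human gene was also compared between utrophin genotypes, as the difference in utrn-/- mice minus the difference in mice with utrophin. S100a8 was at 9.08 in mdx utrn-/- and at the floor of 4 in hDMD mdx utrn-/-, against 4.19 ± 0.01 in mdx and 4.16 ± 0.16 in hDMD mdx. S100a9 was at 9.52 and 4.46, against 4.25 ± 0.29 in mdx and the floor in both hDMD mdx arrays. G0s2 (Entrez 14373), an inhibitor of fat breakdown, had a term of -3.85 ± 0.71. Aldoart2 (Entrez 79459), annotated as an aldolase of germ cells, and Hoxa4 (Entrez 15401), a patterning gene, were at the floor in mdx utrn-/- and at 9.94 and 7.22 in hDMD mdx utrn-/-. Their lowest level in the mdx and hDMD mdx arrays was 8.42 and 6.79, so the terms rest on 1 array at the floor and are not given. No probe set of 7453 passed in limma, 286 had an unadjusted p under 0.05, fewer than the 373 by chance, and the smallest adjusted p was 0.297, for S100a8. With the block S100a8 and Aldoart2 passed, each with an adjusted p of 0.0485 in limma, where for each gene 1 of the 4 genotypes lay at the floor.

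Neutrophil and mast cell genes had a median term of -2.04, with 1 mouse in each utrn-/- genotype, with 8 of 13 lower when adjusted over the list alone, a camera adjusted p of 1.05e-09, and adjusted p = 0.156 with an estimated correlation. Stress genes had a median of -1.02, adipocyte genes of -1.75 and matrix genes of 0.50. Their camera adjusted p values were 1.3e-05, 0.00317 and 0.0176, each with adjusted p = 0.864 with an estimated correlation. Mpo was at -3.15 ± 0.85, Fos at -2.54 ± 0.74, Retn at -5.16 ± 2.28 and Nid1 (Entrez 18073), a basement membrane protein, at 2.10 ± 0.59. Without hDMD mdx 1 the adipocyte and matrix lists did not pass camera (adjusted p 0.0699 and 0.0782), nor did the matrix list without mdx 1 (0.0536) or the adipocyte list with a pseudocount of 1 (-1.94, 0.0674). The utrophin-deficient arrays were all dim, so brightness could not be compared within this term.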

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

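The tests of brightness, carried-along tissue and age in this part, and the counts of splits for single lists, were chosen only after the results were seen. The groups searched for a sample far from the others were the 6 dystrophin-carrying arrays, for 49 genes and 9 lists. Of these 58 groups 9 were picked out, and chance picks out about 1 in 20, or 2.9. For each, the gap to the nearest array is given as a share of the whole range, and lay above Dixon's critical value for 6 arrays. The arrays carrying dystrophin span 4 genotypes, so a genotype can stand out as well as a mouse.

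Wild-type 2 stood apart in the macrophage and monocyte list, with a score of 0.80 against -0.73 to -0.41 (share 0.792), and in the antigen presentation list, with 1.16 against -0.64 to 0.03 (share 0.6254). Brightness is argued against, since the larger difference of dim over bright arrays within mdx and hDMD mdx was 0.353 for this list, far below the gap in wild-type. Fat carried along with the muscle stays open, since the adipocyte score of wild-type 2 was 1.01 above the next array, with Adipoq at 9.70, although hDMD mdx 1 had an adipocyte score of 0.58 and Adipoq at 8.68 with a macrophage score of -0.41. Lymphoid tissue carried along may also be a source, as the lymphocyte score was 0.450 above the next array, but Ighm at 9.04 was no higher than in hDMD at 9.10, which leaves it open. No biological explanation was tested, as both wild-type mice were 7 weeks old and sex and array brightness differ with the mouse.

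Other genes stood apart in wild-type 2. Lgals3 was at 7.53 against 4.23 to 5.13 (share 0.728), C1qb at 7.87 against 5.13 to 5.75 (share 0.773) and Tmsb10 at 8.21 against 6.80 to 7.30 (share 0.643). Mt1 in hDMD mdx utrn-/-, the array with the weakest deposited signal, was at the floor of 4 against 6.39 to 7.29 (share 0.727). Cdkn1a in hDMD mdx 1 was at 4.51 against 6.20 to 6.82 (share 0.732), and Actc1 in the same array at 9.41 against 10.19 to 10.63 (share 0.639). Ucp3 in wild-type 1 was at 5.46 against 7.04 to 7.74 (share 0.694).

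The term for the effect of the human gene by utrophin genotype passed camera for 4 lists. Each utrn-/- genotype was 1 mouse, assumed to vary like the genotypes with 2, so no spread within these genotypes was measured. The median terms were -2.04 for neutrophil and mast cell, -1.02 for immediate early and stress, -1.75 for adipocyte and 0.50 for extracellular matrix genes, and none passed with an estimated correlation.

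The neutrophil and mast cell list was high in mdx utrn-/-, with a score of 2.11, although its mast cell genes Cma1, Cpa3 and Tpsb2 were no higher than in mdx. Csf3r was lower than in mdx 1, the dim array. Blood carried along is argued against, since the blood score of this array was -0.454 relative to the highest other array. Brightness is argued against as well, since S100a8 was 4.88 higher than in mdx 1, which is equally dim. Age cannot be told apart from genotype, since this was the only array (1 of 9) at or under 5 weeks of age. Marrow carried along was not tested, and Mpo (7.17), Elane (6.76), Camp (8.88) and Ngp (8.80) were all highest in this array.

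Extracellular matrix genes had lower values in hDMD mdx than in wild-type. Brightness is argued against, since the smaller of the medians within the bright and the dim arrays was -0.441. Tendon carried along with the wild-type muscle stays open, since tendon genes outside the matrix list had a smaller within-batch median of -0.409, with Chad at 7.34 in wild-type 1 and 6.09 in hDMD mdx 1, although Scx was at 6.87 in hDMD mdx 2 and 5.51 in wild-type 2. Age may also account for part of it: over the 6 dystrophin-carrying arrays r with age was -0.548 (exact permutation p = 0.175) and rho was -0.928 (p = 0.0222), and r was -0.877 without the 2 arrays farthest from the median age. After adjustment over the 26 lists the p for rho was 0.289, so the relation did not pass.

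Other splits of the arrays were counted beside the real ones. In the class comparison 9 probe sets passed, and 3 of 84 splits gave as many, the real one included, a share under 0.05. The other splits were of hDMD, hDMD mdx 2 and hDMD mdx utrn-/-, all dim arrays with the human gene, with 9, and by brightness. The highest other count was 1553, for the split by brightness, which points to a structure of the arrays, and with the block 11 probe sets passed. The arrays are thus not interchangeable, and the share alone does not separate the dystrophin classes from such structure. For the 9 passing lists, 21 of 84 splits gave as many, with a highest other count of 15, so chance is not excluded for that count. List by list, a camera p as small came in 1 of 84 splits, the real one, for regenerating muscle and for glycolysis genes. It came in 5 splits for macrophage, 7 for lysosome, 10 for matrix, 11 for fatty acid oxidation, 20 for stress, 21 for antigen presentation and 26 for complement genes, for which chance is not excluded. A count of 1 in 84 is the smallest possible, and these shares are not adjusted over the 26 lists. The glycolysis list did not pass camera with an estimated correlation (adjusted p = 0.302). For the human gene on deficient backgrounds there were 10 splits, too few for a share under 0.05. No probe set passed there in limma (409 with an unadjusted p under 0.05), 10 of 10 splits gave as many, and the highest other count was 39. The 10 passing lists were reached in 1 split, the real one, and the highest other count was 9.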

How the results depend on the processing

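Among the alternatives given here, brightness as a block, the dim arrays alone, log2 before quantile normalisation and the 100 probe sets with the smallest p were chosen only after the results were seen. Dim signal over background and the number of arrays limit what can be seen: 3.12% of the values used lay at the floor, and no genotype had more than 2 mice. No paired analysis was possible because the labels carry no replicate numbers that link mice across genotypes. Age and sex differ between genotypes. With age as a covariate 7 of the 9 probe sets of the class comparison passed and, for the human gene on deficient backgrounds, 0 in limma (458 with an unadjusted p under 0.05). Without the female mouse 18 passed in the class comparison, 13 higher and 5 lower, all 9 among them. Of the 67 list calls, all 67 kept direction and threshold with a trend in eBayes and with a pseudocount of 64, and 66 with the block and with log2 taken first. With an estimated correlation 1 call remained and with fry 10. A pseudocount of 1 ended 14 calls, no filter 8, the most variable probe set per gene 5, and as deposited 4 were lost and 3 reversed. Without wild-type 2, 11 of its list calls reversed and 6 were lost. Without wild-type 1, 3 reversed and 3 were lost, and without mdx 1 or hDMD mdx 1, 14 and 12 were lost. The cause was not tested for any change given here, except that a fit without a mouse has fewer arrays.

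As deposited, with no normalisation between arrays, 0 probe sets passed in limma in mdx utrn-/- against mdx and in the class comparison (2 and 12 with an unadjusted p under 0.05). The utrn-/- pair had 582 differences over 1 log2 unit and r of -0.0197 with mdx changes. The reversal had r of -0.650 but 53.0% opposite signs (69.9% normalised). Pvalb in mdx against wild-type was at 0.039, and in hDMD mdx against wild-type Matn2, Tnxb, Dgat1, Tyrobp, Ctss, Man2b1 and Grn were at 0.28, 0.099, 0.31, 0.17, 0.076, 0.11 and 0.15. In hDMD against wild-type, Atp5j and Ndufs4 were at -0.16 and -0.078, the neutrophil list at -0.87 and the oxidative phosphorylation list at -0.82. Egr2, Myh7, Ankrd1 and Hspa1a in mdx utrn-/- against mdx were at -0.068, -0.096, -0.027 and -0.11. The macrophage list in hDMD mdx utrn-/- against wild-type was at -1.10, and camera placed it above the other genes.

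Without the filter on dim probe sets, 6 probe sets passed in mdx utrn-/- against mdx, 3 in hDMD mdx utrn-/- against wild-type and 2 in the class comparison. The correlations were 0.0223 in the pair and -0.604 for the reversal. With a pseudocount of 1, the class comparison had 1 passing probe set, mdx utrn-/- against mdx had 0 in limma (407 with an unadjusted p under 0.05), and Dmd in the class comparison was at 0.20. With a pseudocount of 64, Col3a1 and Tnc in mdx against wild-type were at -0.023 and 0.0050, and Utrn in the class comparison was at 0.0083. The trend in eBayes gave 1 passing probe set for the human gene on deficient backgrounds, as did log2 before quantile normalisation, with which Col3a1 in mdx against wild-type was at -0.073. The block gave 4 for the human gene on deficient backgrounds, 2 for its interaction with utrophin, and 0.13 for Cox4i1 in hDMD against wild-type. With the human gene as a covariate 2 probe sets passed in the class comparison, and H2-Aa, Col1a1, Pgam1, Col3a1 and Actc1 were at -0.14, -0.32, -0.29, -0.11 and -0.27, and the matrix list at -0.036. In the dim arrays alone, Col3a1, Actc1, Dmd and Utrn were at -0.074, -0.088, 0.056 and 0.20. Over the 100 probe sets with the smallest p, the correlation was -0.155 in the pair. For the reversal it was -0.900, but these probe sets were chosen on mdx arrays that both comparisons share, so a negative value is partly built in, and no value for unchanged groups was simulated for them.

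Leaving out each mouse in turn, mdx against wild-type gave ranges of -0.27 to 2.09 for Ccl9, -1.42 to 1.62 for Col3a1, -0.19 to 0.38 for Actc1 and -0.49 to 0.43 for Tnc. They were -0.52 to 0.013 for Ckm, -1.20 to 0.59 for Utrn, -1.74 to 0.55 for Acp5, -1.58 to 0.33 for Acads and -2.67 to 0.36 for Lipe. The adipocyte list ranged from -1.91 to 0.23, the lysosome list from -0.089 to 0.57 and the macrophage list from 0.069 to 1.57. In hDMD mdx against mdx, Acads ranged from -0.72 to 2.07, Utrn from -0.71 to 1.12, Ckm from -0.14 to 0.46 and Dmd from -0.072 to 0.099.

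For hDMD mdx against wild-type the ranges were -0.20 to 1.27 for Atp5g1, -0.45 to 1.45 for Cox6c, -1.78 to 0.53 for Cdkn1a, -1.70 to 0.20 for Dgat1 and -1.92 to 0.23 for Cybb. Fabp4 ranged from -1.93 to 0.13, H2-Eb1 from -2.26 to 0.091, Lgals3 from -2.62 to 0.34, H2-DMa from -2.78 to 0.00015 and Col3a1 from -2.93 to 0.11. Its lists ranged from -1.71 to 0.16 (adipocyte), -1.38 to 0.16 (antigen presentation), -0.43 to 0.097 (stress), -0.66 to -0.15 (lysosome), -1.33 to 0.23 (macrophage) and -0.059 to 0.32 (oxidative phosphorylation). In hDMD against wild-type, Cox4i1 ranged from -1.65 to 0.28, and the antigen presentation, lysosome and macrophage lists from -2.28 to -0.10, -0.64 to -0.13 and -1.26 to 0.098.

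In mdx utrn-/- against mdx, 0 probe sets passed in limma without either mdx mouse (218 and 172 with an unadjusted p under 0.05), and Myh7 ranged from -0.45 to 3.50. In hDMD mdx utrn-/- against wild-type, Retn ranged from -4.74 to 0.020, the antigen presentation list from -1.81 to 0.18 and the macrophage list from -1.39 to 0.10. The class comparison ranged from 2 to 18 passing probe sets, and from -0.27 to 0.42 for Actc1, -0.13 to 0.062 for Dmd, -0.38 to 0.51 for Utrn and -0.17 to 0.0013 for Pvalb. Pgam1 on deficient backgrounds ranged from -1.37 to 0.087.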

Other observations

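The comparison of list scores between arrays and the relation with age were chosen only after the scores were seen. Slow fibre contractile genes, which mark fatigue-resistant fibres, varied between mice of the same genotype. Their score was -0.99 in wild-type 2 and 0.68 in wild-type 1, and -1.26 in mdx 1 and 0.73 in mdx 2. In the other 5 arrays it lay between -0.27 in hDMD mdx 2 and 0.69 in mdx utrn-/-. Nerve and Schwann cell genes, which mark motor nerve branches, had scores of -0.48 in wild-type 2 and 0.49 in wild-type 1, -0.26 in mdx 1 and 0.10 in mdx 2, and -0.59 in hDMD mdx 2 and 0.10 in hDMD mdx 1. In these 3 genotypes the dim array had the lower score of both lists, although mdx utrn-/-, also dim, had a nerve score of 0.51. No test of these differences was made.

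Blood genes, mainly of red cells, had scores of 0.67 in hDMD mdx 2 and 0.47 in mdx 1, against -0.61 in hDMD mdx utrn-/- and -0.44 in mdx 2. Adipocyte genes had scores of 1.59 in wild-type 2, 0.58 in hDMD mdx 1 and 0.53 in mdx utrn-/-, and of -0.82 in hDMD mdx utrn-/-.

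Neutrophil and mast cell genes had lower scores in older mice among the 6 dystrophin-carrying arrays, with rho of -0.986 (exact permutation p = 0.00556) and r of -0.744 (exact permutation p = 0.0722). Without the 2 arrays farthest from the median age r was -0.971. Among 26 lists tested in this way the adjusted p for rho was 0.144, so the relation did not pass.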
